A study of Mus musculus with 4 samples.

How the data were processed

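RNA of prostate spheres was measured on 4 arrays with 2 colours, 2 of vehicle-treated and 2 of DAPT-treated spheres. Per the labels, each array carried the RNA of 1 sphere culture sample in the red dye and a universal mouse reference RNA in the green dye, and 2.5 µg of total RNA went into the work-up. No array had the dyes the other way round, so a dye effect on a gene is the same on all 4 arrays and drops out of a difference between groups only as far as it is constant. The direction of every ratio, sample over reference, follows from the dyes named in the labels. The groups and replicate numbers came from the sample titles.

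Per the file headers, each scanner file was written by Agilent Feature Extraction 10.7.3.1 for 1 array, with the spot and local background intensity of both channels as median pixel brightness, not normalized. The same files hold processed intensity values that, per the file headers, the scanner software had background-subtracted and dye-normalized within the array. The deposited log10 ratio of red over green in these files was read only to find the scale and direction of the authors' value table. The authors' deposited value table holds log2 values for the same spots. Set against the scanner ratios of the same array it correlated at 0.869 to 0.902 across spots, so its direction is sample over reference, and its column medians were 0.00072, -0.011, -0.015 and -0.011. How it was normalized is not given in the sources used here. Its values correlated at 0.9996 to 0.9998 with the log ratios computed here.

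Each array held 45018 spots, of which 43379 were probe spots of 41174 probes. The design fixed before the data were examined named mean spot signals. The files used here give median spot signals, which were used in their place. Background was corrected with limma's normexp on the spot and local background intensities with an offset of 50, and loess was fitted within each array with control spots at weight 0. On the DAPT 2 array 13 spots had a local background over 5 times the array's median, up to 29091 against a median of 60, and were left out before normexp. They are also missing in the authors' value table. This choice was made after the intensities had been looked at and before any test, and it matters, since 3 genes were higher and 70 lower with those spots kept. Feature Extraction marked 11.5% of probe spots on vehicle 1, 29.2% on vehicle 2, 49.6% on DAPT 1 and 50.9% on DAPT 2 as non-uniform or as outliers, so these marks differ between the groups. They rose with brightness, from 39.1% on the DAPT arrays in the dimmest of 5 equal groups of probes to 94.3% in the brightest. The standard deviation of the difference between the DAPT arrays was 0.314 (log2) for probes marked on neither, 0.336 for those marked on 1 and 0.315 for those marked on both. This compares the DAPT arrays with each other and cannot show a bias they share. Marked spots were kept, since leaving them out removes most bright genes, and a fit without them is given as an alternative. No probe spot was saturated.

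The probes carry accessions, and 24375 of the 41174 probes were named through the RefSeq transcript accessions of the GRCm38.p6 assembly (17016 symbols). The remaining 16799 probes keep their accession and stand in the tests without a name. The table was used for names only, so no coordinates are given. Spots of a probe were averaged. A probe was kept if Feature Extraction called it well above background in red on both arrays of at least 1 group, and the brightest kept probe stood for its gene, which gave 21464 genes, 13987 of them named. Of 462 other probes of called genes, 68 had the opposite sign and 1 of these passed the threshold. A gene not well above background on either array of a group has only a bound there, given as "at least N-fold". It sets the bright group's mean red signal, after loess and Aquantile normalization, against the higher of the dim probe's own signal and the lowest signal of any probe well above background, and it is open to dye bias. In 23 of the 84 calls with such a group it exceeds the fold of the log ratios, so it is no strict bound, and it is given only where it lies below that fold.

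Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05. Each gene had 2 residual degrees of freedom, and eBayes added 10.3. Gene lists fixed before the data were examined, 25 in all, were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. With an estimated correlation camera rests on the 2 residual degrees of freedom, which leaves it little power. The cholesterol list had an estimated correlation of -0.032, below the preset, and its unadjusted camera p still went from 1.59e-11 to 0.0174. Failing that test thus does not show that correlation between genes made a call. It does not exclude this either. The estimated correlation was 0.479 for the fibroblast and smooth muscle list, 0.185 for the mesenchymal, 0.161 for the cell cycle and 0.102 for the NRF2 list. These lie well above the preset, so camera p-values at the preset may be too small there. The TGF-beta list, like the cholesterol list, lay below it at -0.021. Genes are named by a rule written before the data were examined. It takes the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, leaving out unnamed, predicted and bounded genes, up to 4 members of each list with the smallest p, and a fixed set of genes of Notch signalling, cell type, proliferation and Tgfb. Some genes that the rule names are not reported here. On simulated data with 21464 genes and 2 arrays per group, the test of DAPT against vehicle recovered 46% of 100 genes changed 2-fold and 100% of 100 genes changed 4-fold, with 6 false calls among 152. A list moved by 0.5 (log2) was the 1 list called. The simulated noise was drawn independently for each gene from the fitted variances. The result thus cannot show how the tests fare with correlated genes or with shifts of whole arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

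All 4 arrays lay on 1 slide and in 1 scan, so no slide or scan block could be fitted. The vehicle arrays lay at positions 4 and 3 of the slide and the DAPT arrays at positions 2 and 1, so position and treatment cannot be told apart. The number of arrays limits the precision. The alternatives were the processed intensities, an offset of 10, median centring, scale normalization between arrays, the red channel alone, the authors' table, other filters and probe rules, eBayes with trend and robust, the replicate number as a block, and leaving out each array. The fit with the debris spots kept and the fit without marked spots were added after the data had been seen.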

Results

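Prostate basal cells sorted from adult FVB mice were grown as prostate spheres, a three-dimensional culture in which single epithelial progenitors form clonal balls, with vehicle or with DAPT. DAPT inhibits γ-secretase, the protease that releases the active intracellular part of Notch receptors, and was used at 5 µM with the medium changed every 24 h. The comparison addresses how Notch signalling regulates the proliferation and differentiation of basal cells. Each group had 2 arrays, and each array compared sphere RNA with a universal mouse reference RNA. Median red signal was 1.94 and 1.82 times the local background on the vehicle arrays and 2.85 and 2.42 times on the DAPT arrays, and 63.7% to 69.5% of probe spots were well above background in red. Log ratios of 21464 genes correlated at 0.922 between the vehicle arrays, 0.944 between the DAPT arrays and 0.839 to 0.879 between groups. Nothing in the labels says that the arrays of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. Changes below are log2 fold changes of DAPT over vehicle ± SE from limma with 2 arrays per group, and p-values are Benjamini-Hochberg adjusted over all genes tested unless a list is named.

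Sphere RNA was rich in epithelial keratins relative to the pooled reference in both groups. The log2 ratio of Krt5, a basal keratin, was 4.65 ± 0.03 (SD, n = 2) with vehicle and 4.92 ± 0.35 (SD, n = 2) with DAPT. Krt14, its partner in basal cells, stood at 4.20 ± 0.46 and 4.24 ± 0.10, and the luminal keratin Krt8 at 4.15 ± 0.21 and 3.79 ± 0.19. These levels set the scale only, since the reference is no group of the study.

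The largest fall with DAPT was that of Mmp7, the matrix metalloproteinase matrilysin, at -4.58 ± 0.21 (23.9-fold lower, adjusted p = 7.82e-07). Cyp2f2, a cytochrome P450, fell by 3.95 and Adh1, an alcohol dehydrogenase, fell by 3.26. The other large falls under the naming rule were Ctla2a at -2.78, the stress-response gene Nupr1 at -2.65, S100g at -2.57, Fstl1 at -2.56, the lipoxygenase Alox12 at -2.54, the collagen gene Col5a3 at -2.46, the iron exporter Slc40a1 at -2.45, Mgp at -2.44 and Gabrp at -2.44. The mean log2 red signal of Col5a3 after loess and Aquantile normalization was 10.80 with vehicle and 9.60 with DAPT. Part of its fall in ratio thus lies in the reference channel. The largest rise was that of Igfbp3, which encodes a binding protein for insulin-like growth factors, at 3.18 ± 0.20 (9.09-fold higher, adjusted p = 1.08e-05). Serpinb2 rose by 2.77, Bst1 by 2.55, Slc25a48 by 2.40, Afap1l1 by 2.34, Serpinb10 by 2.27, Degs2 by 2.13, the secreted semaphorin Sema3c by 2.08 and Lmo1 by 1.90. The proliferin genes Prl2c5 and Prl2c3 rose by 3.00 and 2.27, and as near-identical relatives their probes may not tell them apart.

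**Figure D1:**
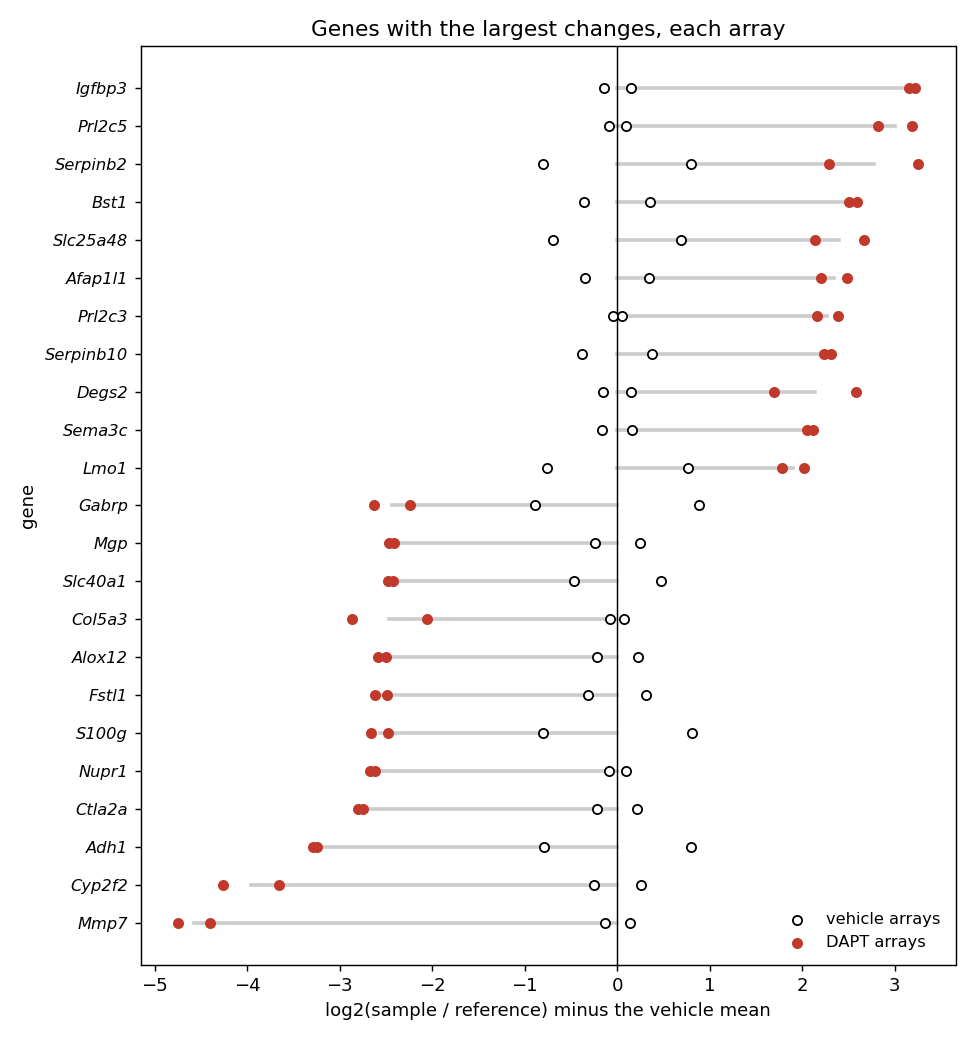
Log2 ratio of sample over reference of each array minus the vehicle mean (x axis) for 11 genes with large rises and the 12 with the largest falls (y axis) under the naming rule. That rule leaves out unnamed, predicted and bounded genes. Open points are the 2 vehicle arrays, filled points the 2 DAPT arrays, and a grey line runs to the DAPT mean. No vehicle point overlaps the DAPT points of its gene, and Mmp7 lies farthest out at a mean of -4.58.

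In all, 622 genes were higher and 843 lower with DAPT (429 and 665 of them named), of which 232 and 422 changed at least 2-fold, and in all 1465 both DAPT arrays lay on the same side of both vehicle arrays. Among the calls, 84 had a group not well above background. The median change over all genes was -0.06. With median centring in place of loess the calls split into 1265 higher and 528 lower (70.6% higher against 42.5%) and the median of all genes moved to 0.11, and with scale normalization between arrays they split into 386 and 1001 (27.8% higher). The sample channel alone, without the reference, called 0 genes with limma (2469 at an unadjusted p under 0.05), keeping the 13 debris spots of DAPT 2 in the background fit left 3 higher and 70 lower (4.11% higher), and leaving out spots marked by the scanner software, which were more common on the DAPT arrays, left 6937 testable genes with 290 higher and 181 lower (61.6% higher).

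Of 18 measured Notch target genes 3 fell with DAPT and none rose, while with the processed intensities only 1 fell. Heyl, a transcriptional repressor induced by Notch, fell by 0.86 ± 0.19 (adjusted p = 0.0205), the receptor gene Notch3 by 0.81 ± 0.21 (adjusted p = 0.0384) and Tnc, which encodes tenascin C, by 1.34 ± 0.22 (adjusted p = 0.00448). After loess and Aquantile normalization the mean log2 red signal was 11.46 with vehicle and 11.09 with DAPT for Tnc. For Notch3 it was 7.49 and 7.23, and for Heyl 8.38 and 7.73. Part of each fall in ratio, most of it for Tnc and Notch3, thus lies in the reference channel. Tnc also belongs to the matrix list, which passed downward in camera. Hes1, the best-known Notch effector, changed by -0.70 ± 0.23 and did not pass (adjusted p = 0.0934). Hes5 at -0.13 ± 0.20 and Nrarp at 0.16 ± 0.28 did not pass either and changed sign under other scalings, and Hey1 and Hey2 were not well above background on both arrays of either group. Adjusted over the list alone, 5 members fell. As a set the targets did not pass in camera (adjusted p = 0.16 over the 25 lists), though they passed with scale normalization, as given below. Heyl lost its call without DAPT replicate 2 (change of -0.86). Notch3 lost its call without vehicle replicate 2 (-0.73) and without DAPT replicate 1 (-0.61).

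Among 31 receptors, ligands and other parts of the Notch pathway, 1 rose and 5 fell. With the processed intensities 0 rose and 1 fell. The ligand gene Jag2 rose by 1.68 ± 0.27 (adjusted p = 0.00381), while Dtx3 fell by 0.76 (not passing without vehicle replicate 1, DAPT replicate 1 or DAPT replicate 2, adjusted p = 0.093, 0.0861 and 0.103), Dlk1 by 1.29 (not passing without vehicle replicate 2, adjusted p = 0.186) and Notch3 as given above. After loess and Aquantile normalization the mean log2 red signal of Dlk1 was 7.70 with vehicle and 7.33 with DAPT. Most of its fall in ratio thus lies in the reference channel. The protease gene Adam10, named after its value was seen, fell by 0.92. Notch1 at 0.36 ± 0.19 and Jag1 at 0.31 ± 0.23 did not pass, and both were below 0 in the sample channel alone. Adjusted over the list alone, 2 rose and 5 fell, and camera gave an adjusted p of 0.265. Without vehicle replicate 2 only 1 member fell, and without DAPT replicate 2 only 3.

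Of 24 basal markers 3 rose and 1 fell. Besides Jag2, Cav1 (caveolin 1) rose by 0.84 ± 0.19 and the laminin receptor gene Itga3 by 0.82 ± 0.21, while the keratin gene Krt15 fell by 1.08 ± 0.20. The mean log2 red signal of Krt15 after loess and Aquantile normalization was 15.46 with vehicle and 11.96 with DAPT. That fall exceeds the fall of the ratio, so its reference signal fell as well. Cav1 did not pass without DAPT replicate 2 (adjusted p = 0.0685), and Itga3 did not pass without vehicle replicate 2 (0.124) or DAPT replicate 2 (0.142). Krt5 at 0.27 ± 0.22, Krt14 at 0.04 ± 0.23 and Trp63, the master regulator of basal cells, at 0.80 ± 0.32 did not pass. Adjusted over the list alone, 4 rose and 3 fell. Without vehicle replicate 1, 5 members rose and 2 fell, without vehicle replicate 2, 2 fell, and without DAPT replicate 1, 3 fell. The list leaned upward without passing (camera adjusted p = 0.0834). It passed upward with the processed intensities (adjusted p = 0.0161), median centring (0.00329, 8 rising and 0 falling), the sample channel alone (0.0176), the filter on all 4 arrays (0.0382), every probe on its own (0.0357), without vehicle replicate 1 (0.00295) and without DAPT replicate 2 (0.012). With scale normalization it passed downward (adjusted p = 0.00917, 2 rising and 5 falling) with Krt14 at -0.86, so its direction is not settled here.

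Of 22 luminal and secretory markers 4 fell and none rose. Among them, Clu (clusterin) fell by 1.95 ± 0.20, the keratin gene Krt19 by 1.11 ± 0.19 and Ceacam1 by 1.06 ± 0.20. Krt8 at -0.36 ± 0.21 and Krt18 at -0.10 ± 0.21 did not pass. The list passed in camera (adjusted p = 0.0151) but not with an estimated correlation (adjusted p = 0.487), its median of -0.14 lay close to that of all genes, and 6 members fell when adjusted over the list alone. It did not pass without vehicle replicate 1 (adjusted p = 0.136), with median centring (0.16) or with the processed intensities (0.118), and with scale normalization it passed with a median of -0.79 (adjusted p = 8.62e-07, 10 members falling and 1 rising).

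Of 28 genes of squamous and keratinocyte differentiation 3 rose and 1 fell. Sprr1b rose by 1.65 ± 0.26, the stress keratin gene Krt16 by 1.59 ± 0.27 and the transglutaminase gene Tgm1 by 0.99 ± 0.20, while Ivl (involucrin) fell by 1.65 ± 0.22. The list had a median of -0.02 and a mean of 0.10 and did not pass (camera upward, adjusted p = 0.315; 5 rose and 2 fell adjusted over the list alone). Without vehicle replicate 1, 5 of its members rose, and without vehicle replicate 2, 2 fell. Of 11 neuroendocrine markers 2 fell, among them Dlk1 at -1.29 ± 0.35 (-0.59 without vehicle replicate 2, and mostly in the reference channel as given above). The neuroendocrine list did not pass (adjusted p = 0.281, with the same number falling when adjusted over the list alone).

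Cell cycle genes rose with DAPT: 16 of 42 passed, none fell, and 26 rose and 1 fell when adjusted over the list alone. With median centring 27 rose, with scale normalization 15 and with the processed intensities 12. The spindle checkpoint kinase gene Bub1b rose by 1.32 ± 0.20, the cyclin gene Ccna2 by 1.21 ± 0.21, the replicative helicase gene Mcm3 by 1.16 ± 0.20 and the topoisomerase gene Top2a by 1.05 ± 0.22. The median of the list was 0.67 (1.59-fold). Mki67 was not analysed here for want of a named probe. Camera gave an adjusted p of 8.05e-14, and the call did not hold with an estimated correlation (adjusted p = 0.479). Without DAPT replicate 2 only 5 members rose, and without vehicle replicate 1 only 8 rose and 1 fell, while the list kept its camera call in both. Top2a did not pass without DAPT replicate 2 (adjusted p = 0.064).

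Genes of cholesterol synthesis and uptake also rose, 7 of 24 past the threshold with none falling, and 15 when adjusted over the list alone. With median centring 16 rose, with the processed intensities 3 and with scale normalization 2, where the list median was 0.28 against 0.60. The sterol sensor gene Insig1 rose by 1.02 ± 0.21, the synthase gene Hmgcs1 by 1.00 ± 0.21 and Pmvk by 0.91 ± 0.23. The list passed in camera (adjusted p = 1.98e-10) but not with an estimated correlation (adjusted p = 0.352), and its passing members numbered 3 without DAPT replicate 2 and 4 without vehicle replicate 1. Pmvk did not pass without vehicle replicate 2 (adjusted p = 0.154) or DAPT replicate 2 (0.0749). Of 31 genes of hypoxia and glycolysis 3 rose, the glycolytic genes Eno1 by 0.96 ± 0.19, Ldha by 0.91 ± 0.19 and Pgk1 by 0.85 ± 0.20, and the angiogenic factor gene Vegfa fell by 0.79 ± 0.21. After loess and Aquantile normalization the mean log2 red signal of Eno1 was 13.53 with vehicle and 13.62 with DAPT. Most of its change in ratio thus lies in the reference channel. Within this list, that signal went from 14.01 to 14.82 for Ldha and from 12.36 to 13.06 for Pgk1. This list did not pass (adjusted p = 0.11; 6 rose and 1 fell adjusted over the list alone), and 5 members rose without vehicle replicate 2. It passed upward without vehicle replicate 2 (adjusted p = 0.0117), with median centring (0.000533, 10 rising and 0 falling), with scale normalization (0.0211), in the sample channel alone (0.0115) and with the filter on all 4 arrays (0.029). Ldha did not pass without DAPT replicate 2 (adjusted p = 0.0525), nor Pgk1 without vehicle replicate 1 (0.0835) or DAPT replicate 2 (0.11). Vegfa did not pass without vehicle replicate 2 (adjusted p = 0.194), without DAPT replicate 1 (adjusted p = 0.0573) or without DAPT replicate 2 (adjusted p = 0.129), and stood at 0.14 in the sample channel alone.

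Genes of TGF-beta signalling and its targets fell: 10 of 37 passed downward and 2 upward, and 19 fell and 3 rose when adjusted over the list alone. The falls numbered 5 with median centring, 4 with the processed intensities and 14 with scale normalization, and the list median of -0.53 became -0.22 in the sample channel alone. Timp1, an inhibitor of metalloproteinases, fell by 2.28 ± 0.21 and the fibronectin gene Fn1 by 2.20 ± 0.20. The ligand gene Tgfb1 fell by 1.02 ± 0.22, Tgfb3 at -0.42 ± 0.23 did not pass, and Tgfb2 was not well above background on both arrays of either group. The mean log2 red signal of Tgfb1 after loess and Aquantile normalization was 10.65 with vehicle and 10.40 with DAPT. Most of its fall in ratio thus lies in the reference channel. Igfbp3 is a member that rose, at 3.18. The other, named after its value was seen, was the integrin gene Itgb6 at 1.02. The list passed in camera (adjusted p = 2.87e-06) but not with an estimated correlation (adjusted p = 0.352). It did not pass on the 8 members left without marked spots (adjusted p = 0.365), some of its members, such as Col1a1, are also markers of fibroblasts, which fell as well, and Tgfb1 did not pass without vehicle replicate 1 (adjusted p = 0.054).

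The matrix and mesenchymal lists leaned downward too, with matrix genes moving both ways. These lists share members, so their falls are in part falls of the same genes. Fn1, Sparc and Mmp2 fell and stand in both lists. Of the matrix genes that fell, Fn1 and Timp1 also stand in the TGF-beta list. Of 37 integrin, laminin and matrix genes 11 fell, among them Sparc (osteonectin) at -2.39 ± 0.19 and the gelatinase gene Mmp2 at -1.92 ± 0.20, and 5 rose, among them Itga3 (14 and 8 adjusted over the list alone; only 2 rose without DAPT replicate 2). Of 15 genes of the epithelial-mesenchymal transition 5 fell, including the mesenchymal transcription factor gene Prrx1 at -2.12 ± 0.21, and none rose (8 and 1 adjusted over the list alone). The median of the mesenchymal list was -0.57, or -0.09 with median centring and -0.14 in the sample channel alone. That of the matrix list was -0.23, and relative to all genes it ranged from -0.47 to 0.006 over the alternatives. Both lists passed in camera (adjusted p = 0.0151 and 2.34e-05) and neither with an estimated correlation (adjusted p = 0.487 for each). The matrix list did not pass with median centring (adjusted p = 0.219) or in the sample channel alone (0.59), and with scale normalization 14 of its members fell and 0 rose. The mesenchymal list did not pass in the sample channel alone (0.0509).

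Markers of fibroblasts and smooth muscle, cell types outside the sorted population, fell as well, 10 of 20 with none rising and 13 when adjusted over the list alone. Postn (periostin) fell by 2.39 ± 0.21, Mgp by 2.44 ± 0.22, the proteoglycan gene Dcn by 1.85 ± 0.23 and the type I collagen gene Col1a2 by 1.85 ± 0.20, and the median of the list was -0.87 (1.83-fold lower), against -0.31 in the sample channel alone. Camera gave an adjusted p of 7.45e-10, lost with an estimated correlation (adjusted p = 0.487). Of 11 endothelial markers 1 rose, Cd34 at 0.99 ± 0.23, of 18 leukocyte markers none passed, and of 10 seminal vesicle and urothelial markers 1 fell, the uroplakin gene Upk1a at -0.81 ± 0.20. Cd34 did not pass without vehicle replicate 1 (adjusted p = 0.0974) or DAPT replicate 2 (0.0581), nor Upk1a without vehicle replicate 1 (0.0793), DAPT replicate 1 (0.0825) or DAPT replicate 2 (0.059). Adjusted over the list alone these numbers were 1 rising, 0 and 2 falling. None of these 3 lists passed (adjusted p = 0.906, 0.16 and 0.281), though the leukocyte list passed downward without vehicle replicate 1 (adjusted p = 0.00555, 2 members falling) and with every probe on its own (0.0303).

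Immediate early genes, which growth factors and cell dissociation induce, fell in 11 of 25 cases with none rising (15 falling and 1 rising adjusted over the list alone). Egr1 fell by 1.94 ± 0.19, the ERK phosphatase gene Dusp6 by 1.47 ± 0.21, the mRNA decay factor gene Zfp36 by 1.39 ± 0.19 and Egr3 by 1.20 ± 0.19. The mean log2 red signal of Dusp6 after loess and Aquantile normalization was 10.90 with vehicle and 10.17 with DAPT. Part of its fall in ratio thus lies in the reference channel. The list median was -0.68, against -0.34 with median centring (7 falling and 1 rising) and -0.40 in the sample channel alone, and camera gave an adjusted p of 6.73e-09 (adjusted p = 0.367 with an estimated correlation). Of 23 genes of the NRF2 and xenobiotic response 4 fell, the glutathione transferase gene Gsta4 by 1.03 ± 0.21, Cyp1b1 by 1.03 ± 0.22, the heme oxygenase gene Hmox1 by 0.83 ± 0.21 and Gsta3 by an amount not given here, since it was not well above background with DAPT (adjusted p = 0.023). Hmox1 did not pass without vehicle replicate 2 (adjusted p = 0.13) or DAPT replicate 1 (0.107), nor Gsta3 without vehicle replicate 2 (0.0597) or DAPT replicate 2 (0.108). Adjusted over the list alone 6 fell. This list passed in camera (adjusted p = 0.00746) but not with an estimated correlation (adjusted p = 0.487) nor with median centring (0.177).

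The remaining lists did not pass, though NF-kB targets passed downward with the processed intensities (adjusted p = 0.0361) and scale normalization (0.00256), interferon-stimulated genes with the processed intensities (0.0361) and p53 targets with scale normalization (0.00133), and ribosomal genes passed upward with median centring (0.0017) and downward with scale normalization (0.00623). Of 26 NF-kB targets 4 fell, Lcn2 by 1.55, the deubiquitinase gene Tnfaip3 by 1.03, Vcam1 by 1.02 and Cxcl5 by 0.90 (list adjusted p = 0.244; 6 adjusted over the list alone). Of 27 interferon-stimulated genes 2 fell, Usp18 by 1.28 and Bst2 by 0.90 (0.315, with 5 falling and 1 rising over the list alone). The mean log2 red signal of Usp18 after loess and Aquantile normalization was 9.29 with vehicle and 8.80 with DAPT. Most of its fall in ratio thus lies in the reference channel. Of 23 p53 targets 2 fell, Btg2 by 1.10 and Gadd45a by 1.06 (0.281; 4 fell and 2 rose over the list alone), and of 27 genes of apoptosis and survival 1 fell, the pro-apoptotic gene Bcl2l11 by 1.44 (0.281; 1 over the list alone). Among 24 genes of the unfolded protein and integrated stress response Asns rose by 1.08 and Pdia6 by 0.77, while Atf3 fell by 1.26 and Ppp1r15a by 1.10 (0.65; 2 rose and 3 fell over the list alone). Of 17 WNT targets and pathway genes Wnt10a rose by 1.26 and the WNT inhibitor gene Sfrp1 by 0.86, and the transcription factor gene Tcf7l2 fell by 1.02 (0.628; 2 and 2 over the list alone; the list median was -0.05 with a mean of 0.02). None of 30 ribosomal protein genes passed, over all genes or over the list alone (0.628). Without vehicle replicate 1 the falls numbered 4 among p53 targets and 2 among the apoptosis and the WNT genes, and 1 stress response gene rose. Without DAPT replicate 2 the falls numbered 1 among interferon-stimulated genes and 2 among the apoptosis and the WNT genes, and 1 stress response gene rose. Without vehicle replicate 2, 2 apoptosis genes fell, and without DAPT replicate 1, 1 WNT gene rose. Calls of single genes were lost for Tnfaip3 and Sfrp1 without DAPT replicate 1 (adjusted p = 0.0573 and 0.0553), for Cxcl5 and Bst2 without DAPT replicate 2 (0.2 and 0.0591) and for Pdia6 without vehicle replicate 1 or DAPT replicate 2 (0.117 and 0.18).

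**Figure D2:**
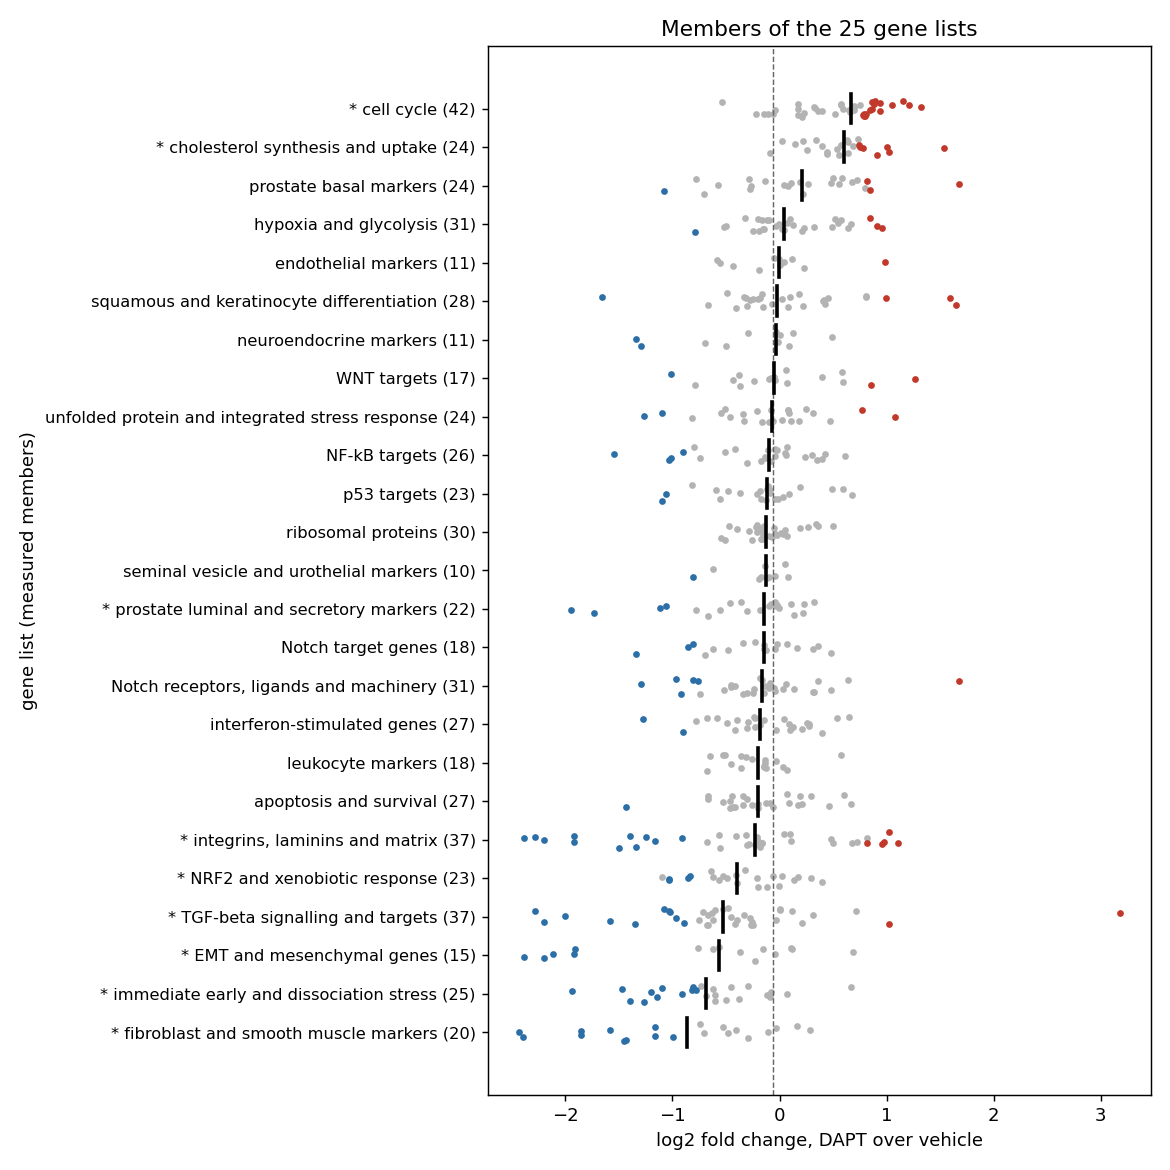
Log2 fold change of DAPT over vehicle (x axis) of the measured members of the 25 gene lists (y axis, number of members in brackets, sorted by median). Coloured points passed the gene test upward (red) or downward (blue), grey points did not, black bars are list medians, the dashed line is the median of all genes at -0.06, and stars mark the 9 lists past the camera threshold. The cell cycle median of 0.67 and the fibroblast and smooth muscle median of -0.87 are the ends of the range. None of the 9 passed with an estimated correlation, a test that rests on 2 degrees of freedom here.

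The reference RNA was the same on every array, so its channel measures what array differences alone give. Comparing the green channel of the DAPT arrays with that of the vehicle arrays called 0 of 21464 genes with limma, with 1586 (7.39%) at an unadjusted p under 0.05 against 2469 (11.5%) in the red channel tested the same way. With median centring in place of quantile normalization 0 genes were called and 1714 had an unadjusted p under 0.05. As the red channel alone called no gene either, the count of 0 in the reference does not show that array differences were small.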

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

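The fit with the debris spots kept and the fit without marked spots were chosen after seeing the data, and all other alternatives before the data were examined. The counts of 622 higher and 843 lower genes became 290 and 337 with the processed intensities, 367 and 524 with an offset of 10, 1265 and 528 with median centring, 386 and 1001 with scale normalization, 0 and 0 with the red channel alone, 3 and 70 with the debris spots kept, 290 and 181 without marked spots, 1160 and 1501 at an adjusted p under 0.1, and 232 and 422 among genes changed at least 2-fold. Leaving out 1 array gave 434 to 805 higher and 616 to 1006 lower genes, the lowest of both without DAPT 2 and the highest of both without vehicle 1. The lone array left in a group is then assumed to vary like the other group. Of the 1465 called genes, 1464 kept their sign with median centring, 1461 with scale normalization, 1451 with the processed intensities, 1392 with the red channel alone and 1457 with the debris spots kept. Without marked spots 458 of them could be tested and 366 stayed past the threshold, and 1007 could not be tested. Fewer genes were testable in that last fit; the cause was not tested for the other shifts. The replicate number did not pair the samples (r = 0.0851 across genes between the replicate differences of the groups), and the replicate block called 888 higher and 1166 lower genes. No slide or scan block was run.

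Of 25 lists 9 passed in camera. This number was 15 with scale normalization, 14 with the debris spots kept, 1 without marked spots (where lists lost members), 0 with an estimated correlation and 3 with fry (TGF-beta, cholesterol and immediate early genes). The cell cycle list passed upward under all 17 settings that tested it with camera at the preset correlation, and did not pass with an estimated correlation (adjusted p = 0.479) or fry (0.0657). The fibroblast, cholesterol and immediate early lists also passed under every such setting that tested them. Without marked spots the cell cycle, fibroblast, cholesterol and mesenchymal lists kept fewer than 5 members and were not tested. An effect of marked spots on these lists is therefore left open. The lists still tested in that fit went through the preranked form of camera, run on limma's t statistics. Their values thus come from a different test than those of the other settings. The luminal list had adjusted p-values of 0.118 with the processed intensities, 0.16 with median centring, 0.0588 with eBayes trend and robust, 0.992 without marked spots, 0.487 with an estimated correlation, 0.0657 with fry, and 0.000538 to 0.136 on leaving out 1 array. The basal list passed upward with the processed intensities (0.0161), median centring (0.00329), the red channel alone (0.0176), a filter on all 4 arrays (0.0382) and every probe on its own (0.0357), passed downward with scale normalization (0.00917), and ranged from 0.00295 to 0.542 on leaving out 1 array. With scale normalization the luminal list passed more strongly (8.62e-07), and in the red channel alone it passed as well (0.0404). The Notch target list passed with scale normalization (0.0318) and with the debris spots kept (0.015), and did not pass on leaving out any 1 array (0.0741 to 0.346). Also gaining a call were the hypoxia list upward with median centring (0.000533), scale normalization (0.0211), the red channel alone (0.0115), the filter on all 4 arrays (0.029), the debris spots kept (0.0246) and without vehicle replicate 2 (0.0117), and downward the NF-kB list with the processed intensities (0.0361), scale normalization (0.00256) and the debris spots kept (0.00173), the interferon list with the processed intensities (0.0361), the p53 list with scale normalization (0.00133) and the debris spots kept (0.0228), the apoptosis list with the debris spots kept (0.0299), the ribosomal list with scale normalization (0.00623), and the leukocyte list with every probe on its own (0.0303) and without vehicle replicate 1 (0.00555). Losing a call were the NRF2 list with median centring (0.177), the red channel alone (0.129) and without marked spots (0.122), the matrix list under the same settings (0.219, 0.59 and 0.365), the TGF-beta list without marked spots (0.365) and the mesenchymal list in the red channel alone (0.0509). The cause was not tested.

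Counts of members past the gene threshold that moved by over 1.5 times in the passing lists included the following. With the processed intensities 2 luminal, 4 TGF-beta, 4 immediate early, 2 NRF2 and 7 matrix genes fell, and 3 cholesterol genes and 1 matrix gene rose. With median centring 2 luminal, 5 TGF-beta, 7 immediate early and 2 NRF2 genes fell, and 27 cell cycle and 16 cholesterol genes rose. With scale normalization 10 luminal genes fell, and 2 cholesterol genes and 0 matrix genes rose. In the red channel alone none passed. Lists that did not pass turned direction as follows, with adjusted p-values. With the processed intensities these were the squamous list (0.952), the unfolded protein list (0.67) and the endothelial list (0.508), and with an offset of 10 the endothelial list (0.963). Median centring turned the WNT (0.639), p53 (0.929), unfolded protein (0.219), endothelial (0.639) and ribosomal (0.0017, now passing upward) lists. Scale normalization turned the squamous (0.206), WNT (0.933), endothelial (0.342) and leukocyte (0.746) lists. The red channel alone turned the unfolded protein (0.59), endothelial (0.778), leukocyte (0.811) and ribosomal (0.601) lists. The filter on all 4 arrays turned the endothelial list (0.959), the mean of a gene's probes the unfolded protein list (0.96), and every probe on its own the WNT (0.742) and unfolded protein (0.5) lists. Keeping the debris spots turned the squamous (0.778), endothelial (0.472) and leukocyte (0.891) lists, and leaving out marked spots the p53, apoptosis and ribosomal lists (0.992 each). On leaving out 1 array the ranges were 0.274 to 0.936 for WNT, 0.306 to 0.95 for the unfolded protein list, 0.663 to 0.95 for the endothelial list and 0.287 to 0.95 for the ribosomal list.

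Of 119 named genes tested 85 were called. Over the alternatives these gave 1458 values, of which 1183 stayed past the threshold in the same direction, 274 did not pass and 1 turned, Vegfa at 0.14 in the red channel alone. On leaving out 1 array the calls lost among the named genes were Dtx3, Pgk1, Pdia6, Cd34, Upk1a and Tgfb1 without vehicle replicate 1, Notch3, Itga3, Dlk1, Pmvk, Vegfa, Gsta3 and Hmox1 without vehicle replicate 2, Notch3, Dtx3, Sfrp1, Tnfaip3, Vegfa, Hmox1 and Upk1a without DAPT replicate 1, and Heyl, Dtx3, Cav1, Itga3, Top2a, Cxcl5, Bst2, Pmvk, Ldha, Pgk1, Vegfa, Pdia6, Gsta3, Cd34 and Upk1a without DAPT replicate 2. Of the genes not called, log2 changes that turned were, with the processed intensities, Zmat3 -0.33, Vwf 0.0876, C1qb 0.0784, Krt20 0.0524, Upk2 0.33, Nrarp -0.50, Jag1 -0.0859 and Krt18 0.02, and with median centring Krt20 0.13, Upk2 0.21, Hes5 0.31, Krt8 0.12, Krt18 0.39 and Tgfb3 0.0370. With loess and scale between arrays they were Hes5 0.0138, Nrarp -0.0405, Jag1 -0.40, Krt5 -0.76 and Krt14 -0.86 (adjusted p = 0.0365), and in the red channel alone Hes5 0.25, Nrarp -0.20, Notch1 -0.16, Jag1 -0.0778, Trp63 -0.0900, Krt18 0.26 and Tgfb3 0.15. With the debris spots kept they were Nrarp -0.20, Notch1 -0.0873, Jag1 -0.75, Krt14 -0.0335 and Trp63 -0.16. On leaving out 1 array the ranges were -0.27 to 0.0129 for Hes5, -0.28 to 0.36 for Krt14, -0.29 to 0.0889 for Krt18, -0.30 to 0.62 for Nrarp and -0.51 to 0.16 for Upk2. Signal over background limits the dim genes: 84 of the calls have a group not well above background.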

Other observations

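The tests of ERK output genes, of fatty acid genes and of the reference channel's share were written down before their results were seen. The tests of marked spots, splits, normalization, stromal cells and epithelial share, and the families below, were chosen only after the results they bear on had been seen. Gene families, taken from the letters that open a symbol, were tested with camera where at least 8 members were measured. Of 247 families 5 passed upward and 4 downward, and none passed with an estimated correlation (adjusted p = 0.929 for each of the 9). That last test rests on 2 degrees of freedom here, so no family was likely to pass it. Collagen genes fell most widely, 13 of 33 past the gene threshold with 1 rising (adjusted p = 2.13e-05), with a median relative to all genes of -0.52, or -0.20 in the red channel alone, and several of them are also fibroblast markers. The largest falls in that family outside the genes already named included Col8a1 at -1.62 ± 0.20, and the gene that rose was Col18a1 at 0.76 ± 0.20, both named after their values were seen. Of 18 matrix metalloproteinase genes 6 fell and 1 rose, Mmp11 falling by 1.92 beside Mmp7 and Mmp2, and Mmp9 rising by 0.95 (adjusted p = 0.0169).

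Nucleoporin genes rose in 4 of 18 cases with none falling (adjusted p = 0.00429), led by Nup107 at 1.33 ± 0.20, and 5 of 10 Mcm genes rose (adjusted p = 0.00382). The chaperonin subunits (Cct, 9 measured), protein arginine methyltransferases (Prmt, 8 measured) and excision repair genes (Ercc, 8 measured) passed as families (adjusted p = 0.0169, 0.0169 and 0.0212) with 0, 1 and 2 members past the gene threshold. Among 66 genes whose symbols open with Atp, 6 fell and 1 rose (adjusted p = 0.0447), with a median relative to all genes of -0.20, or -0.043 with median centring. The 17 genes whose symbols open with Bcl passed downward as a group (adjusted p = 0.0447) with 1 of them, Bcl2l11, past the gene threshold. They share a symbol stem only, and the list of apoptosis and survival genes did not pass (camera adjusted p = 0.281). Relative to the median of all genes, all 9 families kept their direction with median centring, scale normalization, the processed intensities and the red channel alone. Their sizes moved, over these 4 settings, from 0.22 to 0.78 for Cct (0.61 in the fit as reported) and from 0.21 to 0.52 for Prmt (0.51). For Mmp they ranged from -0.53 to -0.33 (-0.14) and for Bcl from -0.40 to -0.075 (-0.28). The strongest falls known only as bounds, named after their values were seen, were Sptssb (at least 11.6-fold lower, adjusted p = 1.11e-05) and the chemokine gene Cxcl13 (at least 6.06-fold lower, adjusted p = 1.11e-05), both not well above background with DAPT.

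For the 1465 calls, 3 technical explanations were weighed. If differences in the reference channel had made the ratios change, that channel would carry most of the change, and it carried a median of 15.0% over the called genes, 5.37% for the higher and 25.7% for the lower ones, so it may add to the falls of some genes. It carried over 50% in 25.6% of the calls. These shares come from background-corrected channels centred on each array's median, without loess. They are thus not shares of the loess ratios that were called, and the reference channel's part in those is not settled. With marked spots left out 366 of the calls (24.98% of all) stayed past the threshold, so the marked values themselves did not make those. Only genes with unmarked values on at least 3 of the 4 arrays were tested in that fit. It thus says little about genes marked on more arrays. Marked spots were left out only after background correction and loess, so an effect through these steps was not tested. For the 1007 calls that could not be tested marked spots and treatment cannot be told apart. The 4 arrays allow only 3 splits into pairs, too few for a share under 0.05, and 1 split, the real one with 1465 calls, gave as many, with 0 calls in the highest of the others.

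The fall of fibroblast and smooth muscle markers may come from fewer stromal cells among the spheres or from lower expression of matrix genes. Of 10 fibroblast markers at least 4-fold above the floor with vehicle, with a median change of -1.52, 2 had 95% intervals wholly above that median, Pdgfra at -0.40 ± 0.21 and Fbln1 at -0.30 ± 0.20. The falls were thus unequal, but other cells could also express these 2, so fewer stromal cells and lower expression cannot be told apart. Of 6 smooth muscle genes as bright, 5 lay above that median too (Tagln, Des, Cnn1, Actg2 and Acta2). Normalization is argued against by the list's median relative to all genes, at most -0.295 over the alternatives (in the red channel alone). In the fit as reported that median was -0.809, so part of the fall in ratio may lie in the reference channel.

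The rise of cell cycle genes could reflect a larger epithelial share of the RNA. The median change of 22 epithelial markers was -0.028 against 0.67 for the 42 cell cycle genes (two-sided permutation p = 5e-05, which treats genes as independent). Of the 22 markers 1 passed the gene threshold, upward. The epithelial median was 0.40 with median centring, 0.20 with the processed intensities, 0.062 in the red channel alone and -0.78 with scale normalization. It was 0.25 without vehicle replicate 1 and -0.22 without vehicle replicate 2, so its direction is not settled. The difference of the medians was 0.52 with median centring, 0.78 with the processed intensities, 0.80 in the red channel alone and 1.41 with scale normalization, with permutation p from 1e-04 to 8e-04. It was 0.94, 0.67 and 0.56 without vehicle replicate 2, DAPT replicate 1 and DAPT replicate 2 (permutation p at most 0.0017), but 0.32 without vehicle replicate 1 (permutation p = 0.0634). The tests lean against a larger epithelial share, but because of that array a larger epithelial share and a rise of cell cycle genes cannot be told apart. Normalization is argued against, since the list's median stayed at least 0.62 above that of all genes over the alternatives. Whether more cells were cycling with DAPT was not tested.

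A hypothesis from the fall of immediate early genes was lower output of the ERK pathway. The 19 measured ERK output genes outside the fixed lists had a median change of -0.13 and did not pass in camera (adjusted p = 0.35 over the 2 hypotheses), with Hbegf and Areg falling by 1.13 and 1.03 and Dusp7 rising by 1.03, so the test did not bear it out. Relative to all genes the median was -0.0886 in the red channel alone and -0.352 with the processed intensities. A hypothesis from the rise of cholesterol genes was that fatty acid genes controlled by the same SREBP factors rose too. The 18 measured had a median of 0.27 and passed in camera (adjusted p = 0.00149) but not with an estimated correlation (adjusted p = 0.27), and 3 passed the gene threshold, Elovl6 at 1.08, Aacs at 0.95 and Fasn at 0.71. This is consistent with a wider rise of SREBP targets, as a hypothesis only, and relative to all genes the median was 0.0853 with scale normalization.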
